A study of Mus musculus with 12 samples.

How the data were processed

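RNA was measured in differentiated 3T3-L1 cells, a mouse preadipocyte line that turns into lipid-filled adipocytes under a hormone cocktail. Per the labels' protocols, treatment ran from day 0 to day 8 of differentiation, maintenance medium held insulin at 5 µg/ml, and RNA was taken at day 8. The labels give 4 treatments: vehicle (ethanol and DMSO), alpha-linolenic acid (ALA) at 50 µM in medium with 2% fatty-acid-free albumin, a delta-6-desaturase inhibitor at 5 µM, and both together. The labels state albumin only for the medium with ALA and vehicle only for control. Whether albumin, ethanol and DMSO were matched between the arms is not given in the sources used here. Each treatment had 3 arrays, from cells of passage 6, 7 and 8. The labels state an RNA integrity number above 8.9 for every sample and 100 ng of total RNA as input. Samples were grouped by the treatment in their labels, and arrays are named here by group and passage. The passages belong to 1 cell line, so p-values for single genes measure the spread between cultures of that line.

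The values were log2 signals deposited by the authors, with 1 value per transcript cluster and array, made with RMA per the submitters' processing notes. RMA corrects background, normalizes across arrays and summarises the probes of a cluster. Its software, version and library file were not given in the sources used here. The table held 22104 clusters on 12 arrays, all of which entered the tests with no filter and no further scaling. Arrays give no read depth, and the number of arrays limits the precision. RMA moves the signal of dim clusters toward a common floor, so differences between low signals are understated and noisy.

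Gene symbols came from the array's annotation as held by GEO, which named 19509 clusters with 1 symbol each and left 2595 unnamed here. All 19509 carried an ID found in the RefSeq gene table, and 0 of them had another symbol there. The named clusters stood for 19480 genes. Where a gene had more than 1 cluster (29 further clusters), the cluster with the highest mean over the 12 arrays was used. Genomic positions were not used here.

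Tests were run in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. One linear model with a coefficient per treatment was fitted to all 12 arrays (8 residual degrees of freedom), followed by eBayes (4.66 prior degrees of freedom). A cluster was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The series design names an unadjusted p under 0.01, so that count is given beside the 221 clusters, or 1% of all, that chance alone would give. The series lists ALA against control, inhibitor against control, and both against ALA alone. The comparison of both against the inhibitor alone, and the interaction of ALA with the inhibitor, follow from the layout. The design text speaks of weighted least squares without naming the weights, so array weights were run as an alternative.

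Before the data were examined, 32 gene lists, the tests, the rule for named genes and most alternatives were fixed. The lists covered long-chain polyunsaturated fatty acid (PUFA) synthesis, de novo lipogenesis, cholesterol synthesis and uptake, PPAR-responsive genes, mitochondrial fatty acid oxidation, adipocyte differentiation, preadipocyte and fibroblast markers, extracellular matrix, triacylglycerol synthesis, lipolysis and lipid droplets, fatty acid uptake, thermogenic markers and oxidative phosphorylation. They also covered inflammatory and acute-phase genes, interferon-stimulated genes, eicosanoid enzymes and lipid receptors, the unfolded protein and integrated stress response, NRF2 targets, cell cycle, p53 targets, insulin signalling, glycolysis and hypoxia, LXR targets, AHR targets, circadian clock, immediate early genes, heat shock and ribosomal proteins. Markers of macrophages, endothelium, muscle, and osteoblasts and chondrocytes stood for other cell types. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list moves at all, were run beside it. Camera sets the genes of a list against the other genes, and the preset fixes their correlation. A camera p-value at the preset therefore does not measure the spread between cultures. Some list members were not analysed here.

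The named genes were, in each comparison, up to 10 higher and 10 lower genes with the largest change at an adjusted p under 0.05. Where fewer passed, places were filled by the smallest unadjusted p under 0.01 among genes that differed the same way in all 3 passages. The rule also named Fads2, Fads1, Elovl5 and the fixed markers Angptl4, Pdk4, Plin2, Scd1, Fasn, Insig1, Adipoq, Pparg, Fabp4 and Lep, and up to 4 members with the smallest p of each list described. Only part of the genes so named is printed, and that part was chosen with their values in view.

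Passage numbers were checked for pairing by correlating each array's deviations from its group mean, before the calls of the fits were compared. Only in ALA plus inhibitor against ALA was every same-passage correlation over 0.1 (0.16, 0.16 and 0.24 for passages 6, 7 and 8). For that comparison the value with passage as a block is given beside the result. The pairing comes from the passage numbers in the labels and is not stated as a shared day or batch.

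The code was tested on simulated data built from the spread of ALA against control over 22104 clusters. A log2 change of 0.5 was recovered for 9.8% of changed clusters at the adjusted threshold and for 58.4% at the unadjusted threshold. A log2 change of 1 was recovered for 86.0% and 98.3%. There were 4.7 false adjusted calls per simulation on average. For lists, simulated over 19480 independent genes, 1 list of 20 genes shifted by 0.20 was called in 19 of 20 simulations with 0 false lists. Real genes of a list vary together, which that simulation left out.

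Alternatives were passage as a fixed or random block, array weights, an intensity trend with a robust prior, only the arrays compared, arrays centred on their medians, quantile normalization, leaving out the dimmest 30% of clusters, averaging clusters per gene, and leaving out each array or passage. Fits without the ALA array of passage 7, in comparisons that do not use it or together with the block, were added after seeing the data, as were fits pooling the layout.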

Results

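Transcript levels were measured on 12 whole-transcript arrays of 3T3-L1 adipocytes at day 8 of differentiation, 3 arrays per treatment. ALA is the plant omega-3 fatty acid, and the delta-6-desaturase, the product of Fads2, is the first enzyme on its way to longer and more unsaturated fatty acids. The table held log2 signals of 22104 transcript clusters, from 1.56 to 13.4, with array medians between 6.14 and 6.27. All means below are over 3 arrays and are given with their SD. The ALA array of passage 7 stood apart. Its correlations with the other arrays were 0.976 to 0.987 across clusters, against 0.989 to 0.994 among the other 11 arrays.

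The first comparison asked what ALA did to the differentiating cells. Genes of cholesterol synthesis and uptake fell together with ALA. Of the 19 measured, 18 were lower and 1 was higher, with a median log2 change of -0.21, and the list averaged 9.99 ± 0.10 with ALA and 10.21 ± 0.08 in control. Sc5d, a sterol desaturase late in the pathway, measured 10.96 ± 0.10 with ALA and 11.36 ± 0.07 in control, a log2 difference of -0.40 (SE 0.11). The differences were -0.49 for Cyp51 (lanosterol demethylase), -0.30 for Sqle (squalene epoxidase) and -0.29 for Insig1, which holds the sterol sensor complex in the endoplasmic reticulum. Camera gave the list an adjusted p of 1.8e-10, and an adjusted p = 0.3 with an estimated correlation. Exact permutation of the cultures gave the list mean p = 0.1, the smallest that 3 against 3 can give. Adjusted over the list alone, 1 gene was lower (Sc5d, adjusted p = 0.044), and over all clusters 0 passed. The list mean was lower in 3 of 3 passages. The labels state albumin only for the ALA medium, so each difference with ALA is between ALA in medium with albumin and an arm whose albumin is not given.

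The long-chain PUFA synthesis genes went both ways with ALA. Fads2 measured 12.38 ± 0.03 with ALA and 12.62 ± 0.04 in control, a log2 difference of -0.24 (SE 0.09, limma adjusted p = 1). Fads1, the delta-5-desaturase, differed by -0.24 and the elongase Elovl5 by -0.26. Elovl2, another PUFA elongase, was at 4.85 ± 0.13 with ALA and 4.26 ± 0.25 in control, both below the array median. Its log2 difference was 0.60 (limma adjusted p = 0.017, adjusted over the list alone). Of the 10 measured genes 3 were higher and 7 lower, and camera gave an adjusted p of 0.18. Fry's test for change in either direction gave an adjusted p of 0.0013, and its directional test 0.82. Camera with an estimated correlation gave an adjusted p of 0.68, and exact permutation of the cultures gave the list mean p = 0.6.

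Other lists also fell with ALA at the preset correlation, each with an adjusted p of 0.042. With an estimated correlation the adjusted p was 0.4 for LXR targets, 0.78 for glycolysis and hypoxia genes and 0.68 for immediate early genes. Exact permutation of the cultures gave these list means p = 0.1, 0.2 and 0.3 in that order. LXR targets, the oxysterol-responsive genes, had 11 of 12 members lower and a median log2 change of -0.10. Among them Apoc1, an apolipoprotein, measured 8.79 ± 0.36 against 9.41 ± 0.11 in control, Scd1 (the stearoyl-CoA desaturase) differed by -0.22 and the cholesterol exporter Abca1 by -0.25. Glycolysis and hypoxia genes had 18 of 23 members lower and a median of -0.09, with Vegfa at -0.32. Immediate early genes had 15 of 20 lower and a median of -0.08, with Ier3 at -0.50 and Nr4a1 at -0.27. Quantile normalization ended all of these calls (LXR 0.1, glycolysis 0.13, immediate early 0.09), the LXR call also ended with only the 6 arrays compared (0.056) and the glycolysis call without the dimmest 30% of clusters (0.051). De novo lipogenesis had 10 of 14 genes lower (median -0.09, adjusted p = 0.15), and Fasn differed by -0.15.

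Adipocyte markers went both ways with ALA, 14 of 27 higher and 13 lower (adjusted p = 0.96). The members with the smallest p were Apoc1 (-0.63), Car3, a carbonic anhydrase abundant in fat (10.72 ± 0.47 against 10.08 ± 0.37, 0.64), Nrip1 (-0.45) and Lep (leptin, 8.13 ± 0.21 against 7.79 ± 0.33), each with a limma adjusted p of 1. Adipoq, which encodes adiponectin, measured 13.05 ± 0.10 against 13.06 ± 0.10, Pparg 11.82 ± 0.01 against 11.78 ± 0.03, and Fabp4 12.92 ± 0.21 against 12.99 ± 0.10. Of the PPAR-responsive genes 10 were higher and 12 lower (adjusted p = 0.86), with differences of -0.36 for Plin5, 0.27 for Ehhadh, -0.19 for Angptl4, -0.04 for Pdk4 and -0.09 for Plin2. Preadipocyte and fibroblast markers had 11 of 18 higher, with a median of 0.01 (adjusted p = 0.86).

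No cluster passed the adjusted threshold in limma for ALA against control, where the smallest adjusted p was 0.695 for the cytochrome P450 gene Cyp2j13 (-0.71). With passage as a block, array weights or an intensity trend the count was also 0. At an unadjusted p under 0.01 there were 116 clusters, 67 higher and 49 lower, fewer than the 221 that chance alone would give, and at p under 0.05 there were 753 against 1105. The smallest p among higher genes belonged to Cyb5rl (0.52), Cyp4a29 (0.58) and Inpp5j (0.57), and among lower genes to Cyp2j13, Olfr1297 (-0.60) and St8sia5 (-0.70). The share of higher clusters was 57.8%, and it was 60.7% with arrays centred on their medians and 48.3% after quantile normalization. Of the 116 clusters 84.5% lay below the array median. Without the ALA array of passage 6 there were 281 clusters, without that of passage 8 there were 188, and without that of passage 7 there were 130, of which 55 were higher and 75 lower. The list count of 4 went to 2 without control 6, 1 without control 7, 7 without ALA 7 and 1 without ALA 8. The glycolysis call ended without control 6 (adjusted p = 0.12), control 7 (0.16), ALA 7 (0.09) or ALA 8 (0.35), the LXR call without control 6 (0.058), 7 (0.06) or 8 (0.12) or ALA 8 (0.26), and the immediate early call without control 7 (0.23) or 8 (0.12) or ALA 6 (0.074) or 8 (0.26). Leaving passage 7 or 8 out of every group also ended each of these calls (0.32 and 0.31 for glycolysis, 0.072 and 0.46 for LXR, 0.33 and 0.31 for immediate early genes).

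**Figure D1:**
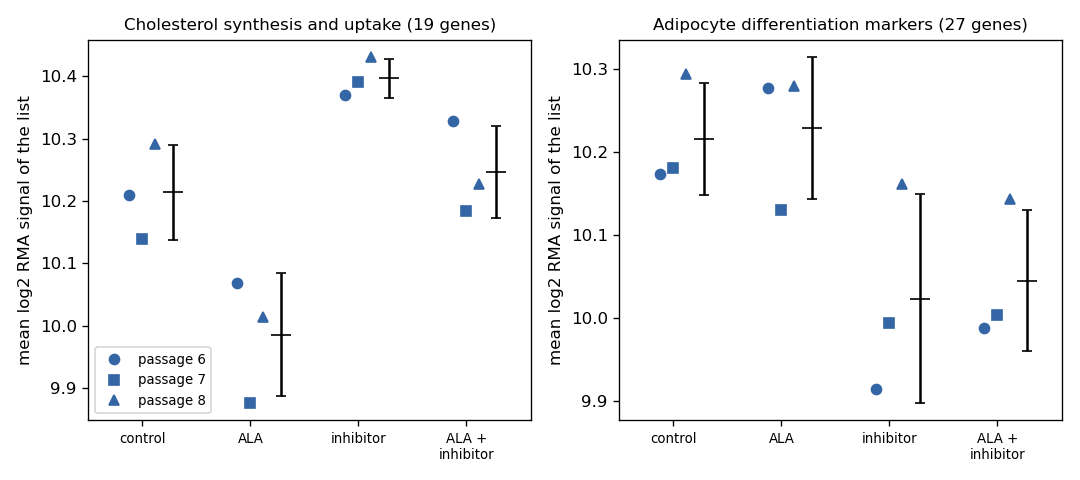
Mean log2 signal of the 19 cholesterol synthesis and uptake genes and of the 27 adipocyte differentiation markers on each array. Points are arrays, with a symbol per passage, and bars are the group mean ± SD of 3 arrays. The cholesterol list averaged 9.99 ± 0.10 with ALA and 10.40 ± 0.03 with the inhibitor, and the adipocyte list 10.02 ± 0.13 with the inhibitor and 10.22 ± 0.07 in control.

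The second comparison asked what the delta-6-desaturase inhibitor did without added ALA. The values are transcript levels only, so effects of the compound outside the enzyme cannot be told apart from a block of the enzyme. Cholesterol synthesis and uptake genes rose with the inhibitor, 18 of 19 higher with a median log2 change of 0.18, and the list averaged 10.40 ± 0.03 against 10.21 ± 0.08 in control. Lss, the lanosterol synthase, measured 11.22 ± 0.07 against 10.88 ± 0.07, a log2 difference of 0.34 (SE 0.11). The differences were 0.30 for Mvd, 0.26 for Fdps and 0.48 for Idi1, enzymes of the mevalonate and isoprenoid steps. The camera adjusted p was 3.1e-06, and 0.47 with an estimated correlation. Exact permutation of the cultures gave the list mean p = 0.1. Fads2 measured 12.77 ± 0.04 against 12.62 ± 0.04 in control (difference 0.15, limma adjusted p = 1) and Fads1 11.78 ± 0.04 against 11.57 ± 0.09.

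Markers of mature adipocytes and of preadipocytes both fell with the inhibitor. Of the adipocyte markers 21 of 27 were lower, with a median log2 change of -0.08 and a mean of -0.19 (adjusted p = 7e-04, and adjusted p = 0.47 with an estimated correlation). Pck1, which makes glycerol precursors for triacylglycerol, measured 8.36 ± 0.82 against 9.32 ± 0.30, Apoc1 differed by -0.57, the adipogenic transcription factor Cebpa by -0.26 and the glycerol channel Aqp7 by -0.57. Adipoq measured 13.10 ± 0.11 against 13.06 ± 0.10, Pparg 11.72 ± 0.13 against 11.78 ± 0.03 and Fabp4 12.95 ± 0.06 against 12.99 ± 0.10. Of the preadipocyte and fibroblast markers 17 of 18 were lower, with a median of -0.17 (adjusted p = 0.002, and adjusted p = 0.5 with an estimated correlation). Exact permutation of the cultures gave p = 0.1 for the adipocyte list mean and 0.3 for the preadipocyte list mean. Dlk1, the preadipocyte factor, measured 11.25 ± 0.13 against 11.57 ± 0.03, and the stromal genes Cd34, S100a4 and Sox9 differed by -0.35, -0.37 and -0.39.

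Lipolysis and lipid droplet genes fell with the inhibitor, 15 of 18 lower with a median of -0.13 (adjusted p = 0.0081, and adjusted p = 0.47 with an estimated correlation). Among them were Mgll, the monoacylglycerol lipase, at -0.55, Pde3b at -0.28 and Aqp7, also an adipocyte marker, at -0.57. Exact permutation of the cultures gave p = 0.2 for the lipolysis list, and 0.1 each for the inflammatory and stress response lists below. Inflammatory and acute-phase genes fell, 24 of 28 lower with a median of -0.10 (adjusted p = 0.0084, and 0.47 with an estimated correlation), among them Hp (haptoglobin) at -0.62, Il1rn at -0.39, Orm1 at -0.48 and Lcn2 at -0.25. NRF2 antioxidant genes rose, 21 of 23 higher with a median of 0.15 (adjusted p = 0.00039, and 0.47 with an estimated correlation), with Nqo1 at 0.29 and Txnrd1 at 0.25. The unfolded protein and integrated stress response list rose, 21 of 28 higher with a median of 0.12 (adjusted p = 0.0045, and 0.47 with an estimated correlation), with the serine synthesis gene Phgdh at 0.36 and Atf3 at 0.33. Slc7a11, the cystine transporter, is a member of both and differed by 0.30. Ribosomal protein genes rose, 21 of 22 higher with a median of 0.11 (adjusted p = 7e-04, and adjusted p = 0.52 with an estimated correlation), with Rps4x at 0.19 and Rpl37 at 0.18.

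No cluster passed the adjusted threshold in limma for the inhibitor against control (smallest adjusted p 0.828). There were 189 clusters at an unadjusted p under 0.01, 71 higher and 118 lower, fewer than the 221 expected by chance. At p under 0.05 there were 955 against 1105. Among lower genes the smallest p belonged to Kif18b (-0.58), the adipokine gene Nrg4 (-0.65), Apol10b (-0.70), Prss21 (-0.65), Klk11 (-0.72) and Zfp940 (-0.62). Ffar4, the long-chain fatty acid receptor, was at -0.98 and Sctr, the secretin receptor, at -0.98. The smallest p among higher genes belonged to Vmn2r121 (0.66, from 2.35 ± 0.10 in control) and Ttpa (0.78, from 2.89 ± 0.15). The share of higher clusters among the 189 was 37.6%, and it was 61.6% with arrays centred on their medians and 51.2% after quantile normalization. Without the ALA array of passage 7, which enters only the shared spread, there were 293 clusters. The list count of 8 went to 1, the cholesterol list, without inhibitor 6, to 4 without control 8 and to 15 without inhibitor 8. Without inhibitor 6 the adjusted p was 0.069 for adipocyte markers, 0.13 for preadipocyte markers, 0.36 for lipolysis, 0.36 for inflammatory genes, 0.066 for NRF2, 0.069 for the stress response and 0.066 for ribosomal genes. Without control 8 it was 0.088, 0.21, 0.21 and 0.15 for the first 4 of these. Leaving passage 6 out of every group ended the lipolysis (0.17), inflammatory (0.11) and stress response (0.13) calls, and leaving out passage 7 the ribosomal call (0.13).

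**Figure D2:**
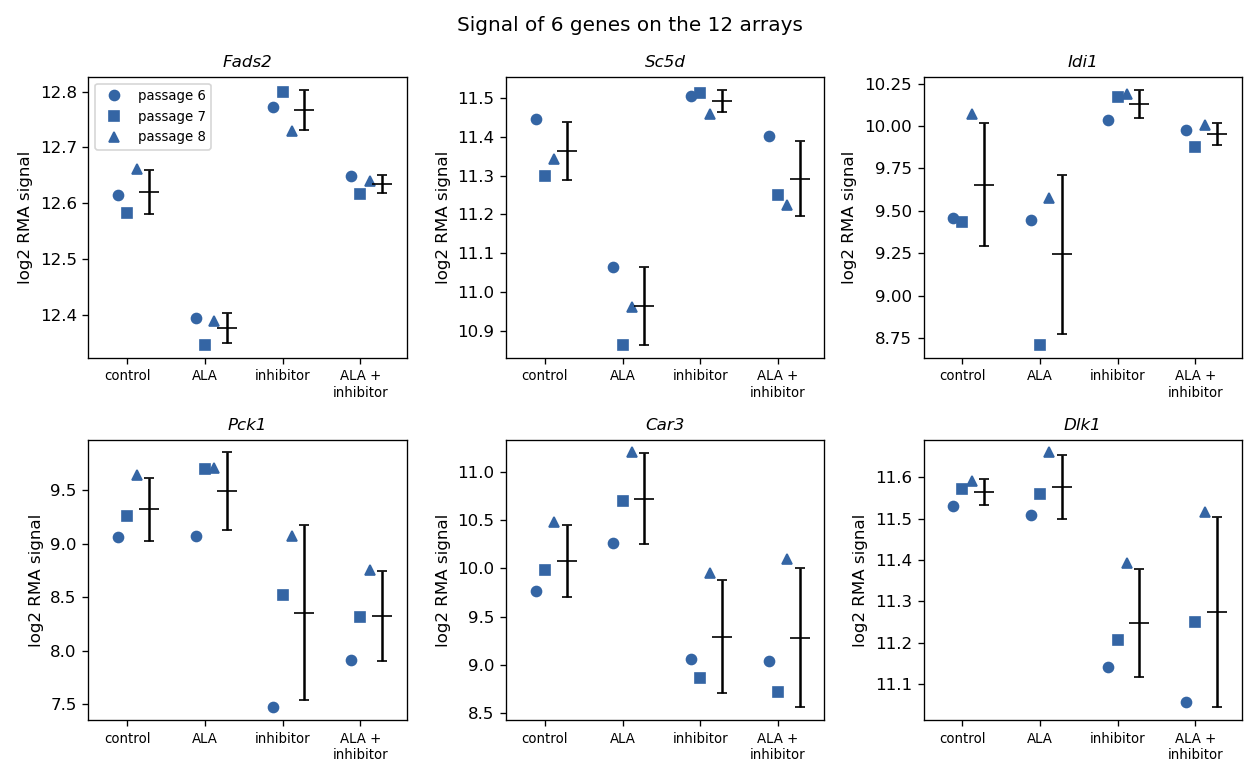
Log2 signal of Fads2, Sc5d, Idi1, Pck1, Car3 and Dlk1 on each of the 12 arrays, with a symbol per passage and bars for the group mean ± SD of 3 arrays. Axes differ between panels. Fads2 lay at 12.38 ± 0.03 with ALA and 12.63 ± 0.02 with ALA plus inhibitor, and Dlk1 at 11.25 ± 0.13 with the inhibitor and 11.57 ± 0.03 in control.

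The third comparison asked what the inhibitor did to cells given ALA. Cholesterol synthesis and uptake genes rose, 19 of 19 higher with a median log2 change of 0.25, and the list averaged 10.25 ± 0.07 with both against 9.99 ± 0.10 with ALA alone (adjusted p = 1.9e-09, 6.8e-10 with passage as a replicate block, and adjusted p = 0.38 with an estimated correlation). Idi1 measured 9.95 ± 0.07 against 9.24 ± 0.47, a log2 difference of 0.71 (SE 0.22), and Sc5d 11.29 ± 0.10 against 10.96 ± 0.10, a difference of 0.33. Pmvk differed by 0.46 and Insig1 by 0.39. Adjusted over the list alone, 6 genes were higher (smallest adjusted p 0.041), and over all clusters 0 passed. Fads2 measured 12.63 ± 0.02 against 12.38 ± 0.03 (difference 0.26, limma adjusted p = 0.65, and 0.4 with the block), Fads1 differed by 0.30 and Elovl5 by 0.19. The PUFA synthesis list had an adjusted p of 0.28 by camera (0.22 with the block) and 0.02 by fry's test for change in either direction.

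The stress and antioxidant lists rose as well in this comparison. The unfolded protein and integrated stress response list had 25 of 28 genes higher and a median of 0.14 (adjusted p = 0.00014, 3.6e-05 with passage as a replicate block, and adjusted p = 0.49 with an estimated correlation), with Slc7a11 at 0.35, the transcription factors Atf3 at 0.34 and Atf4 at 0.24, and Aldh1l2 at 0.42. NRF2 genes had 20 of 23 higher and a median of 0.11 (adjusted p = 0.00029, 5.5e-05 with the block, and adjusted p = 0.49 with an estimated correlation), with Nqo1 at 0.39, Gsta3 at 0.31 and Hmox1 at 0.31, and Slc7a11 again a member. Ribosomal protein genes had 20 of 22 higher and a median of 0.11 (adjusted p = 0.00037, 0.00019 with the block, and adjusted p = 0.56 with an estimated correlation), with Rps25 at 0.40 and Rpl27 at 0.39.

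Preadipocyte and fibroblast markers fell, 16 of 18 lower with a median of -0.22 (adjusted p = 0.012, 5.5e-05 with passage as a replicate block, and adjusted p = 0.56 with an estimated correlation). Thy1 differed by -0.35, Dlk1 by -0.30 and S100a4 by -0.46. Thermogenic adipocyte markers fell, 14 of 16 lower with a median of -0.18 (adjusted p = 0.022, 0.038 with the block, and adjusted p = 0.49 with an estimated correlation). The thermogenic list averaged 5.66 against 5.67 in passage 6, 5.40 against 5.83 in passage 7 and 5.57 against 5.63 in passage 8. Most of the fall thus lay in passage 7, whose ALA array stood apart. Dio2, the deiodinase, differed by -0.38 (3.74 against 4.12, both below the array median) and Cox7a1 by -0.36. Of the adipocyte markers 17 of 27 were lower, with a median of -0.09 (adjusted p = 0.07, called with the block at 0.017, and adjusted p = 0.46 with the block and an estimated correlation). Car3 measured 9.28 ± 0.72 against 10.72 ± 0.47 (difference -1.44, SE 0.37, limma adjusted p = 0.65, and 0.19 with the block), Pck1 8.32 ± 0.42 against 9.49 ± 0.36 (adjusted p = 0.65, and 0.29 with the block), and Bscl2 (seipin) 8.51 ± 0.15 against 9.06 ± 0.30. Adipoq measured 13.10 ± 0.09 against 13.05 ± 0.10.

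No cluster passed the adjusted threshold in limma for ALA plus inhibitor against ALA (smallest adjusted p 0.653). There were 325 clusters at an unadjusted p under 0.01, 110 higher and 215 lower, more than the 221 expected by chance. At p under 0.05 there were 1607 against 1105. The smallest p belonged to Gtf2h4 (0.68) among higher genes and to Gm3893 (-0.68), Gm10591 (-0.67) and Tmem182 (-0.65) among lower genes. The share of higher clusters was 33.8%, and it was 46.9% with arrays centred on their medians and 46.4% after quantile normalization. With passage as a replicate block there were 561 clusters (smallest adjusted p 0.185) and 9 lists, the further ones being adipocyte markers (adjusted p = 0.017, lower), extracellular matrix (adjusted p = 0.036, lower) and oxidative phosphorylation (adjusted p = 0.039, higher), with adjusted p = 0.46, 0.46 and 0.51 with an estimated correlation. Without ALA 7 there were 186 clusters, 91 higher and 95 lower, fewer than the 221 expected by chance. Without ALA 6 there were 624, and without ALA plus inhibitor 6 there were 185. The thermogenic call ended without ALA 6 (adjusted p = 0.058), ALA 7 (0.14) or ALA plus inhibitor 7 (0.3), and the preadipocyte call without ALA 8 (0.19) or ALA plus inhibitor 6 (0.17) or 7 (0.085). Leaving passage 7 out of every group ended the NRF2 (0.091), ribosomal (0.2), preadipocyte (0.22) and thermogenic (0.67) calls. There were 14 lists without ALA plus inhibitor 8.

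**Figure D3:**
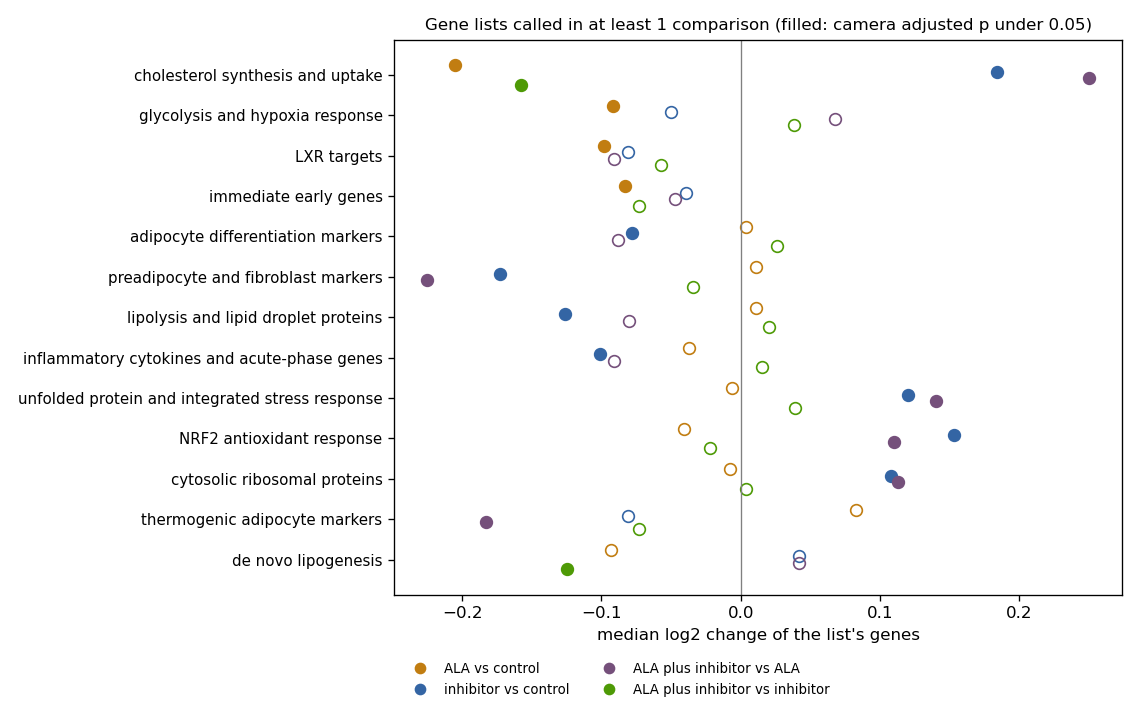
Median log2 change of the 13 gene lists called in at least 1 comparison, with a colour per comparison and filled points for a camera adjusted p under 0.05 at the preset correlation. Cholesterol synthesis and uptake was filled in all 4 comparisons, from -0.21 for ALA against control to 0.25 for ALA plus inhibitor against ALA.

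The layout also gives the effect of ALA when the inhibitor was present. Cholesterol synthesis and uptake genes fell, 19 of 19 lower with a median log2 change of -0.16, and the list averaged 10.25 ± 0.07 with both against 10.40 ± 0.03 with the inhibitor alone (adjusted p = 3.6e-05, and adjusted p = 0.77 with an estimated correlation). Mvd differed by -0.25, Sc5d by -0.20, Hsd17b7 by -0.19 and Lss by -0.18. De novo lipogenesis genes fell, 14 of 14 lower with a median of -0.13 (adjusted p = 0.012, and adjusted p = 0.77 with an estimated correlation). Acaca, the acetyl-CoA carboxylase, measured 8.62 ± 0.12 against 8.95 ± 0.07, and 8.67 ± 0.10 in control. Elovl6, Acly and Acss2 differed by -0.31, -0.15 and -0.21. The lipogenesis list averaged 9.01 ± 0.18 with both, 9.15 ± 0.14 with the inhibitor alone and 9.04 ± 0.08 in control. Against control, the inhibitor alone had 11 of the 14 genes higher (median 0.04, camera adjusted p = 0.07). The fall is thus from an inhibitor mean above control to a mean near control. Of the PUFA synthesis genes 9 of 10 were lower, with a median of -0.12 (adjusted p = 0.074), including Fads2 at -0.13 and Fads1 at -0.16. Adipocyte markers had 16 of 27 higher (adjusted p = 0.73).

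No cluster passed the adjusted threshold in limma for ALA plus inhibitor against the inhibitor (smallest adjusted p 1). There were 161 clusters at an unadjusted p under 0.01, 72 higher and 89 lower, fewer than the 221 expected by chance. At p under 0.05 there were 786 against 1105. The smallest p belonged to Clgn (0.67) and Elf5 (0.76) among higher genes and to Ica1l (-0.74) and Olfr250 (-0.71) among lower genes. The lipogenesis call ended without inhibitor 6 (adjusted p = 0.1), inhibitor 7 (0.087) or ALA plus inhibitor 8 (0.3). Leaving passage 7 out of every group ended both calls (0.23 for lipogenesis, 0.058 for cholesterol), and leaving out passage 8 ended the lipogenesis call (0.078). There were 4 lists without inhibitor 6 and 4 without inhibitor 8.

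Whether ALA acted differently with and without the inhibitor was tested by the interaction. Camera called 0 lists, as did an estimated correlation and fry's directional test, and the smallest adjusted p was 0.15 for glycolysis and hypoxia genes (20 of 23 higher, median 0.11). For the cholesterol list the mean interaction was 0.08 on the log2 scale (95% interval -0.12 to 0.27), for de novo lipogenesis -0.07 (-0.40 to 0.27) and for adipocyte markers 0.01 (-0.24 to 0.26). The interaction was 0.11 for Fads2 (-0.18 to 0.40), 0.20 for Sc5d (-0.13 to 0.52) and -0.69 for Elovl2 (-1.15 to -0.22, limma adjusted p = 1). No cluster passed the adjusted threshold in limma (smallest adjusted p 1). There were 141 at an unadjusted p under 0.01, 54 higher and 87 lower, fewer than the 221 expected by chance. At p under 0.05 there were 755 against 1105. The smallest p belonged to Cyp2j13 (0.73) and Il1rn (1.02) among positive values and to Plce1 (-0.96) and Krtdap (-0.87) among negative values. Of the 141 clusters 93.6% lay below the array median. Without ALA 7 there were 211 clusters, 126 higher and 85 lower. There was 1 list called without ALA 6, without inhibitor 7 or without inhibitor 8.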

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

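The adjusted count stayed at 0 in every comparison under every setting, and 0 of the gene or list results that had passed their threshold changed direction. For genes this says little, because only the named genes were followed. Most of those that passed had been picked for an unadjusted p under 0.01 and the same direction in every passage. Leaving out a whole passage could therefore not reverse them. Of the values for the named genes, counted over comparisons and settings, 5590 kept their direction and their side of the unadjusted threshold. A further 111 came to pass it and 223 no longer passed it. The other 92 had not passed it and changed direction. For single lists, at the adjusted threshold, these counts were 3069, 104, 97 and 314. Counts at an unadjusted p and list counts moved most. Fits without the ALA array of passage 7 in comparisons that do not use it, or together with the block, were chosen after seeing the data. Where leaving out an array left fewer arrays, and where dim clusters were left out, the number tested fell by construction, and otherwise the cause was not tested. Most clusters at an unadjusted p under 0.01 lay below the array median, where signal over background is least.

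Counts at an unadjusted p under 0.01 follow, in the order ALA against control, inhibitor against control, ALA plus inhibitor against ALA, ALA plus inhibitor against inhibitor, and interaction. With passage as a fixed replicate block they were 186, 322, 561, 234 and 207, and as a random replicate block 182, 294 and 518 for the first 3 and 217 for the interaction. With the replicate block and without ALA 7 they were 178, 472, 322, 326 and 250. With array weights the inhibitor gave 438, ALA plus inhibitor against inhibitor 370 and the interaction 280. With an intensity trend and a robust prior ALA plus inhibitor against inhibitor gave 106. Only the 6 arrays compared gave 60 for ALA and 188 for ALA plus inhibitor against ALA. Without the dimmest 30% of clusters the counts were 51 for ALA, 110 for the inhibitor, 76 for ALA plus inhibitor against inhibitor and 57 for the interaction. Leaving out an array or a passage gave 82 (passage 8) to 281 (ALA 6), 112 (passage 6) to 293 (ALA 7), 135 (passage 7) to 624 (ALA 6), 99 (passage 6) to 233 (ALA 7), and 92 (passage 6) to 211 (ALA 7).

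For lists, ALA against control had 9 with array weights, 8 with an intensity trend and robust prior and 1 after quantile normalization, and the interaction had 1 with the trend. With an estimated correlation 0 lists were called in ALA against control, 0 in inhibitor against control, 0 in ALA plus inhibitor against ALA and 0 in ALA plus inhibitor against inhibitor, and with fry's directional test also 0, 0, 0 and 0. Fry's test for change in either direction called PUFA synthesis and cholesterol in ALA against control (0.0013 and 0.026) and in ALA plus inhibitor against ALA (0.02 and 0.02). Leaving out an array or a passage gave 1 to 7 lists, 1 to 15, 3 to 14, 0 to 4 and 0 to 1 in the order above.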

Other observations

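Of the 32 lists, 19 were called in no comparison in the fit without a block. With passage as a replicate block, extracellular matrix was called lower with the inhibitor against control (adjusted p = 0.016, and adjusted p = 0.4 with an estimated correlation) and p53 targets higher (0.047, and 0.4 with an estimated correlation). De novo lipogenesis, not among the 19, was also called higher with the inhibitor against control in that fit (adjusted p = 0.043, and 0.26 with an estimated correlation). AHR targets were called lower with ALA against control (just under the threshold, 0.05 as rounded, and adjusted p = 0.38 with an estimated correlation), besides the lists named above for ALA plus inhibitor against ALA. In the fit without a block the lowest adjusted p of the 19 by camera were 0.056 for AHR targets (ALA against control, median -0.15), 0.067 for PUFA synthesis (inhibitor against control, 0.06), 0.072 for oxidative phosphorylation and 0.072 for muscle markers (both in ALA plus inhibitor against ALA, 0.05 and -0.16), 0.083 for p53 targets (inhibitor against control, 0.13), and 0.095 for circadian clock and 0.095 for endothelial markers (ALA against control). Mitochondrial fatty acid oxidation, extracellular matrix, interferon-stimulated genes and macrophage markers had 0.18, triacylglycerol synthesis 0.2, insulin signalling 0.24, heat shock 0.25, cell cycle 0.3, PPAR-responsive genes 0.32, fatty acid uptake 0.46, osteoblast and chondrocyte markers 0.65 and eicosanoid enzymes 0.72.

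Averaging the inhibitor effect over cells with and without ALA, with passage as a replicate block, gave 8 lower genes at an adjusted p under 0.05. They were Car3 (-1.11), Pck1 (-1.07), B3galt2 (-0.94), Arxes1 (-0.84), the transcription factor gene Osr2 (-0.84), the Wnt antagonist gene Sfrp2 (-0.78), the lipocalin gene Apod (-0.68) and Hp (-0.59), each lower in 6 of 6 passage pairs, with an adjusted p from 0.023 to 0.037. This fit was chosen after the data were seen, among 4 fits of 2 effects. The 8 genes were also picked on the same 6 pairs, so being lower in all of them adds no separate support. Without the block 0 genes passed, with and without ALA 7, and with the block and without ALA 7 there were 3, Osr2, Apod and 1 unnamed cluster (adjusted p = 0.044 each). The other 6 of the 8 genes then had an adjusted p from 0.057 to 0.13. The average ALA effect gave 0 in all 4 fits. The pairing of passages met its criterion only in ALA plus inhibitor against ALA. Swapping the inhibitor label within passage pairs gave as many genes in 1 of 32 splits, the real split, and the highest other had 1. That is the smallest share 32 splits can give, and these swaps were run only for the inhibitor fit with the block.

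Across all clusters the ALA effect without and with the inhibitor correlated at 0.036 (-0.063 without ALA 7), and the inhibitor effect without and with ALA at 0.29 (0.12 without ALA 7). At an unadjusted p under 0.01 in both, there were 4 clusters for ALA, 3 of them with the same direction, and 7 for the inhibitor, 6 of them with the same direction. Independent tests would give 0.416 and 1.5 with the same direction, but both effects use 1 variance per cluster from 1 fit, which raises the count passing in both without a shared effect. These pairs of effects share no array.

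The tests in the next paragraphs were chosen after the results were seen, except the test of signal range and the splits. The ALA array of passage 7 had an SD of difference from the other arrays of 0.406, the others at most 0.261. Against the other ALA arrays its median difference was 0.255 among clusters of median level 5.11 and -0.12 among those of median level 8.16. A narrower signal range alone would be removed by quantile normalization, and afterwards the SD was still 1.55 times the highest of the others, which argues against it as the whole cause. A less differentiated culture would lower adipocyte and raise preadipocyte markers, and these lay at percentiles 15.2 and 91.2 of level-matched lists, in that direction but inside the spread, so it stays open. No other biological explanation was tested.

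The cholesterol list was lower with ALA and higher with the inhibitor, in 6 of 6 passage pairs each (mean log2 difference -0.19 and 0.22). The outlying ALA array alone could not account for the ALA call, as its adjusted p was 1.2e-06 without that array. A shift of all bright genes is also argued against, since the list lay at percentile 0 of level-matched lists for ALA and 100 for the inhibitor. Permuting treatment over whole cultures gave an exact p of 0.005 for each effect, the smallest possible. Against the largest of the 32 lists it was 0.125 for ALA (0.16 with swaps within passage pairs), so chance shifts of cultures stay open there. For the inhibitor it was 0.02 over whole cultures, which argues against them. Swaps gave 0.031 for the inhibitor, the smallest that 64 swaps can give. Extracellular matrix also reached 0.031 with swaps, at an exact p of 0.33 over whole cultures. The swaps therefore do not set the cholesterol list apart.

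Adipocyte and preadipocyte markers were both lower with the inhibitor, in 6 of 6 passage pairs each. A smaller share of adipocytes in the dish would raise preadipocyte markers, whose median was -0.193, at percentile 0 of level-matched lists, with an exact p of 0.09 over whole cultures and 0.031 with swaps within passage pairs. A shift of all genes at that level is argued against by percentile 0 of the adipocyte list among level-matched lists. Chance shifts of cultures gave the adipocyte list an exact p of 0.015 alone, and against the largest of the 32 lists 0.17 over whole cultures and 0.031 with swaps. The percentiles compare genes and not cultures, the spread between cultures argues against a smaller share and against chance only where passages are taken as pairs, and pairing met its criterion in 1 of the 2 comparisons pooled here, so both stay open.

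The triacylglycerol synthesis list was also lower with the inhibitor in 6 of 6 passage pairs (-0.079, exact p = 0.01, and 0.04 against the largest of the 32 lists). Of 64 such list tests over whole cultures, 13 had an exact p under 0.05 and 0 passed after adjustment (smallest adjusted p 0.14). The smallest possible exact p was 0.005, so a pass after adjustment needed several lists at that value together. That 0 passed therefore says little.

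Other divisions of the same 6 arrays into 3 and 3 are too few, at 10, for a share under 0.05. As many clusters at an unadjusted p under 0.01 came from 8 of 10 splits for ALA against control (116, highest other 1045), 4 of 10 for inhibitor against control (189, highest other 400), 2 of 10 for ALA plus inhibitor against ALA (325, highest other 457) and 3 of 10 for ALA plus inhibitor against inhibitor (161, highest other 247), the real split included. As many lists came from 4 of 10 (4, highest other 7), 3 of 10 (8, highest other 11), 2 of 10 (6, highest other 15) and 8 of 10 (2, highest other 13), so the preset correlation also called lists in divisions that mix the treatments. For ALA against control some splits gave several times the real count of clusters, and the cause was not tested. For the interaction 52 of 100 splits gave as many clusters (141, highest other 1050), and with a real list count of 0, all 100 of 100 splits had to give as many lists (highest other 13), so that count tests nothing.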
